A study of Arabidopsis thaliana with 12 samples.

How the data were processed

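Gene expression was measured in the third and the fourth leaves of Arabidopsis thaliana of the Col ecotype and of gvs1-1, at the stages that the labels call DAE14 and DAE28. The labels do not spell out DAE, and the locus of gvs1 is not given in the sources used here. Per the labels, plants grew on soil for 23 and 37 days under 16 h of light and 8 h of dark, and leaves were taken 5 h after the lights came on. Each of the 4 groups had 3 biological samples, 12 in all, each hybridised to 1 array. Total RNA was amplified and labelled with Cy3 with a one-colour Agilent kit, per the labels' protocols.

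The deposited files of the single arrays are scanner output of Agilent Feature Extraction, version 11.5.1.1 per the file headers and 11.5 per the submitters' processing notes. They give spot intensities on a linear scale, and the processed signal used here is the background-corrected intensity that the authors' extraction software computed per spot. A table of the whole series holds the authors' log2 values for 21266 loci. These tracked the log2 median signal of each array, with a correlation of at least 0.995 on every array across 13416 loci that have 1 probe, which is a correlation across genes and not across samples. The array medians of that table lay between 8.86 and 8.91; its scaling between arrays is not given in the sources used here. The table served only as an alternative.

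Each array carried 43603 probes after control spots were left out. RefSeq accessions in the files matched 34348 probes to 25410 loci of the TAIR10.1 assembly table, and 9255 probes had no match. The files name the TAIR10 build, so no coordinates are printed. Spots of one probe were averaged, 166 probes with an outlier mark on any array were left out, and 0 spots were saturated. The log2 processed signal of each array was expressed relative to its 75th percentile. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which held for 26801 probes with a locus. The probe with the highest mean over all arrays stood for its gene, giving 19152 genes. Among the 5874 genes with several kept probes, probes were called in opposite directions in 56 genes for age in Col, in 32 for age in gvs1-1 and in 3 for the genotype comparison at DAE28.

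The number of arrays limits the precision, and so does the signal over background. The 75th percentile of the processed signal ran from 700.0 to 891 at DAE14 and from 1169 to 1567 at DAE28, and 63.8% to 72.5% of spots were well above background. A gene not well above background on any array of a group has only a bound there. It is given as "at least N-fold", the mean of the bright group against the mean of a per-array floor in the dim group, where the floor was the higher of the lowest signal among probes well above background and the gene's own signal.

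Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 12 arrays with 4 group means. The contrasts were DAE28 minus DAE14 in each genotype, gvs1-1 minus Col at each stage, and the interaction, which is the age change in gvs1-1 minus that in Col. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, all tests were two-sided, and values are log2 differences ± SE. The p-values measure the spread between samples grown and hybridised as these were. The relative size of the age response in gvs1-1 was the summed age change of the genes that passed and changed at least 2-fold in a fit of stage alone, divided by that in Col, with an exact permutation of genotype labels within stage. In settings with a block the labels were permuted in the same way, across the blocks, so the permutation p is not exact there.

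There were 28 gene lists with 475 entries, of which 449 were measured; root markers, with 1 of 4 members measured, and seed markers, with 0 of 4, were not tested. The other 26 lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They covered senescence-associated genes, senescence transcription factors, chlorophyll breakdown and synthesis, light-harvesting antenna, photosystem subunits, carbon fixation, plastid ribosomal proteins, autophagy, nutrient remobilisation, salicylic acid, jasmonate, abscisic acid, ethylene, cytokinin, the circadian clock, redox enzymes, heat shock proteins, flavonoids, glucosinolates, cell division, phase change, and markers of guard cells, vascular tissue, epidermis, and flowers and meristems. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were companions. At the preset correlation 16, 16, 4, 13 and 14 lists passed, in the order age in Col, age in gvs1-1, genotype at DAE14, genotype at DAE28 and interaction, and with an estimated correlation 0 passed in each of the 5 comparisons. By fry 16, 16, 4, 13 and 12 of these passed.

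Named genes followed a rule. Per comparison it took the 5 largest rises and falls among genes with a symbol that passed, were well above background on every array compared and whose groups did not overlap, up to 4 members with the smallest adjusted p per list, a panel of 10 genes and the 2 largest bounds in each direction. It added up to 5 genes per direction called alike in both genotype comparisons. For the interaction all 12 arrays had to be above background and overlap was not asked about. The rule, the lists, the comparisons and the main settings were fixed before the data were examined. So were these alternatives: quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes and a filter over all arrays, the mean of a gene's probes, trended and robust variance, array weights, only the 2 groups compared, the replicate number as a block, slide and scan day as blocks, the authors' table, each probe on its own, a 2-fold minimum, and each array left out in turn. Normexp took the median spot signal, where the plan had named the mean signal. Slide as a random block, the arrays of scan day 1 alone, and slides 1 and 3 alone were chosen after seeing the data.

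Slide 1 held the 3 Col DAE14 arrays and Col DAE28 replicate 1, slide 2 held Col DAE28 replicates 2 and 3 and gvs1-1 DAE14 replicates 1 and 2, and slide 3 held gvs1-1 DAE14 replicate 3 and the 3 gvs1-1 DAE28 arrays. Slides 1 and 3 were scanned on day 1 and slide 2 on day 2. In simulated data for 19152 genes with the spread of these arrays, 100 genes had a log2 change of 1 and 100 one of 2. The changes were set at gvs1-1 DAE28 alone, with independent noise. For age in gvs1-1 the fit recovered 61% of genes with a log2 change of 1 and 88% of those with 2. For the genotype comparison at DAE28 it recovered 58% and 85%, and for the interaction 32% and 76%. Far more genes were called in the data, and the adjusted threshold depends on that share, so these values are not the recovery there. A simulated relative size of 70% was found as 71.3%, and one of 100% as 100.7%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.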

Results

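Transcript levels were profiled in ageing Arabidopsis leaves of Col, the reference ecotype, and of gvs1-1; per the series title the question was how leaf senescence transcriptomes differ between them. The third and the fourth leaves were sampled at the stages called DAE14 and DAE28, with 3 biological samples per genotype and stage, each on its own one-colour array. Of the 19152 genes tested, 13786 changed with age in Col and 11750 in gvs1-1, while 60 differed between the genotypes at DAE14 and 6337 at DAE28. Arrays of one group correlated at 0.972 to 0.992 across genes and arrays of different groups at 0.766 to 0.988; genes are not independent replicates in these values. The locus of gvs1 is not given in the sources used here, so its transcript was not set against the genotypes.

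In Col leaves, lists of senescence and nutrient remobilisation genes rose from DAE14 to DAE28 while lists of photosynthesis and cell division genes fell. These list calls passed at the preset correlation and were lost with an estimated one (adjusted p = 0.203 to 0.248). The cysteine protease gene SAG12, a classical senescence marker, was not well above background at DAE14 and was at least 6093-fold higher at DAE28 (limma adjusted p = 2.6e-06). The senescence regulator NAP rose by 3.77 ± 0.21 and the chlorophyll degradation gene NYE1, also called SGR1, by 4.28 ± 0.18 on the log2 scale (SE, n = 3 arrays per stage; limma adjusted p = 2.2e-07 and 8.0e-08). RBCS1A, a small subunit of Rubisco, fell by 2.06 ± 0.11 and the antenna gene LHCB2.2 fell by 1.59 ± 0.14. In all, 6843 genes rose and 6943 fell, and 3400 rose and 4323 fell by at least 2-fold.

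The largest changes are named among genes that have a symbol, lie well above background on every array compared and do not overlap between the groups. Within this limit the largest rises in Col were SRG1 with 8.59 ± 0.63, PYD4 with 8.01 ± 0.44, the alternative oxidase AOX1D with 7.62 ± 0.70, the mitochondrial carrier BAC2 with 7.18 ± 0.30 and the transcription factor NAC047 with 7.07 ± 0.31. The largest falls within that limit were the myrosinase TGG2 with -9.32 ± 0.34, the arabinogalactan protein FLA2 with -8.32 ± 0.41, the proline-rich protein PRP4 with -8.15 ± 0.71, the tonoplast aquaporin DELTA-TIP with -7.35 ± 0.52 and the cell wall enzyme XTH6 with -7.31 ± 0.45. Among genes below background at one stage, the protease inhibitor KTI1 was at least 831-fold higher at DAE28, and the expansin EXPB1 and the auxin-response gene SAUR26 were at least 113-fold and 75.4-fold lower. Of the remaining panel genes, NAC6, also called ORE1, rose by 4.39 ± 0.62, WRKY53 rose by 1.36 ± 0.53 and the clock gene CCA1 fell by 0.70 ± 0.20. PR1 (1.87 ± 1.25, adjusted p = 0.20) and FT (0.61 ± 0.37, adjusted p = 0.16) did not pass.

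Of 19 senescence-associated genes 17 rose in Col, such as YLS7 by 2.21 ± 0.12 and SAG29 by 9.47 ± 0.67. Of 31 senescence transcription factors 24 rose and 3 fell, with WRKY45 at 4.67 ± 0.15 and MYB2 at 5.98 ± 0.30. The list medians were 2.84 and 2.41 (camera adjusted p = 2.9e-06 and 4.6e-06; adjusted p = 0.203 with an estimated correlation for both). Of 23 autophagy genes 20 rose, including ATG8B by 2.94 ± 0.17 and APG7 by 3.21 ± 0.23 (median 1.11; adjusted p = 0.212 with an estimated correlation). Of 24 nutrient remobilisation genes 16 rose and 3 fell, with the acid phosphatase PAP17 at 4.56 ± 0.20 and the glutamate dehydrogenase GDH2 at 4.37 ± 0.20 (median 1.32; adjusted p = 0.231 with an estimated correlation). The abscisic acid and water deficit list had 22 rises and 3 falls among 27, including RD20 with 4.54 ± 0.25 and HAI2 with 3.97 ± 0.30 (median 1.48; adjusted p = 0.212 with an estimated correlation). Of 22 salicylic acid and immunity genes 13 rose, such as GRX480 by 3.68 ± 0.42 (median 1.76; adjusted p = 0.677 with an estimated correlation). Of 12 heat shock proteins 11 rose, such as HSP70 by 3.09 ± 0.27 (median 2.01; adjusted p = 0.323 with an estimated correlation).

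The photosynthetic apparatus moved the other way in Col. All 24 chlorophyll synthesis genes fell, among them GUN5, the H subunit of magnesium chelatase, with -3.75 ± 0.18 and CHLM with -3.35 ± 0.17, and so did 20 of 21 antenna genes, all 23 photosystem subunits, all 20 carbon fixation genes and all 21 plastid ribosomal proteins. The list medians were -2.68, -2.52, -2.25, -2.48 and -2.69, and the adjusted p with an estimated correlation lay between 0.203 and 0.248. PSBQA fell by 3.81 ± 0.14, LHCB4.1 fell by 2.29 ± 0.11, PGK1 fell by 2.94 ± 0.13 and RPL12-A fell by 2.48 ± 0.11. Cell division genes fell in 13 of 14 cases (median -2.60; adjusted p = 0.231 with an estimated correlation), for example the mitotic kinase CDKB2;1 with -2.79 ± 0.15. Markers of other leaf cell types fell at the same time: 8 of 9 vascular markers, with a median of -4.35 (adjusted p = 0.293 with an estimated correlation), and all 6 epidermis and trichome markers, with a median of -1.75 (adjusted p = 0.212 with an estimated correlation). The sieve element gene SEOR1 fell by 4.35 ± 0.26 and the epidermal regulator ATML1 fell by 2.53 ± 0.12. Under quantile normalization the antenna and photosystem medians were -0.94 and -0.99.

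Chlorophyll breakdown and flavonoid genes were more mixed. Of 14 chlorophyll breakdown genes 8 rose and 5 fell, and the list did not pass (median 1.56, camera adjusted p = 0.097), although PPH rose by 2.87 ± 0.09 and MES16 by 3.31 ± 0.17. Of 15 flavonoid and anthocyanin genes 9 rose and 1 fell, with the anthocyanin regulator PAP1 (AT1G56650) at 6.59 ± 0.44 and the list median at 4.40 (camera adjusted p = 0.029; adjusted p = 0.677 with an estimated correlation). The mean of that list relative to Col DAE14 was 3.70 ± 1.94 (SD, n = 3 arrays) and ranged from 1.61 to 5.43 between the Col DAE28 arrays. Its call was lost with quantile normalization (median 3.31), median centring (4.57), slide (2.25) or scan day (3.31) as a block, on scan day 1 or slide 1 alone (2.25), in the authors' table (2.96), with only genes above background on all arrays (0.54) and without Col DAE28 replicate 3 (3.73). The value of 2.25 rests on 1 DAE28 array, replicate 1, which had the lowest mean of this list. For every list tested in Col, the counts adjusted over the list alone were the same as those over all genes.

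With slide as a fixed block 12112 genes changed with age in Col, with scan day as a fixed block 12952, on the arrays of scan day 1 alone 12225 and on slide 1 alone 11963. Scan day 1 and slide 1 held a single Col DAE28 array, replicate 1, assumed to vary like the others. With slide as a block the age changes in Col also rest on this array, so they are no separate check. The medians of the senescence-associated and photosystem lists were 3.27 and -2.58 with slide as a block and on slide 1 alone, and 2.90 and -2.37 with scan day as a block. The median change of all genes was 0.01 here, 0.12 under quantile normalization, 0.18 with median centring and -0.33 without the filter on dim probes, where 38.3% of the called genes rose instead of 49.6%.

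**Figure D1:**
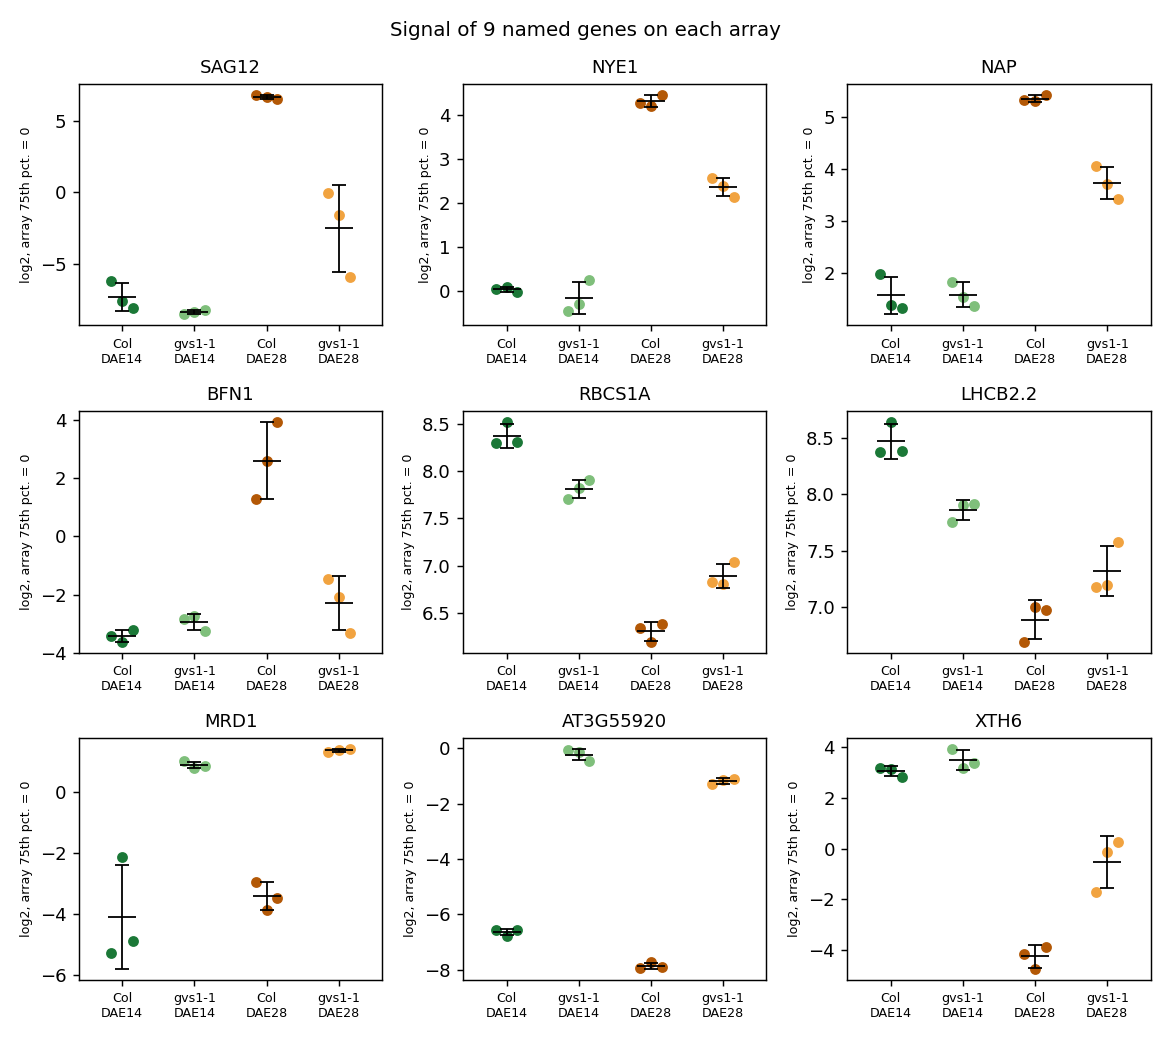
Signal of 9 named genes on each array, as log2 processed signal with the array's 75th percentile at 0. Points are the 3 arrays of a group, the bar is the mean and the whiskers are the SD; SAG12 was not well above background at DAE14 and ranged widely in gvs1-1 at DAE28 (mean -2.51, SD 3.04).

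In gvs1-1 leaves, the senescence and photosynthesis lists moved in the same directions with age as in Col, at the preset correlation but not with an estimated one (adjusted p = 0.243 to 0.255). NAP rose by 2.14 ± 0.21, NYE1 by 2.53 ± 0.18 and NAC6 by 2.90 ± 0.62, and RBCS1A fell by 0.92 ± 0.11 (SE, n = 3 arrays per stage; limma adjusted p = 1.7e-05, 3.3e-06, 0.0023 and 4.9e-05). SAG12 was at least 16.5-fold higher at DAE28 than at DAE14, where it was not well above background (limma adjusted p = 0.0016). With 1 array left out its log2 change ranged from 4.62 to 7.55, so its size depends on single arrays. Altogether 6007 genes rose and 5743 fell, of which 2274 and 3184 changed at least 2-fold. WRKY53 (0.68 ± 0.53, adjusted p = 0.29), PR1 (2.12 ± 1.25), CCA1 (0.16 ± 0.20) and FT (-0.22 ± 0.37) did not pass. LHCB2.2 fell by 0.54 ± 0.14, but under quantile normalization, which moved the median of all genes from 0.06 to 0.12, its value was 0.21.

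Within the same limit the largest rises in gvs1-1 were the protein kinase CIPK25 with 6.81 ± 0.60, the calmodulin-like gene CML41 with 5.94 ± 0.71, PYD4 with 5.84 ± 0.44, the transcription factor MYB112 with 5.71 ± 0.37 and the cation exchanger CHX17 with 5.45 ± 0.56. The largest falls within it were the expansin EXPA8 with -8.31 ± 1.34, TGG2 with -7.29 ± 0.34, FLA2 with -7.11 ± 0.41, MSRB6 with -6.62 ± 1.23 and the arabinogalactan protein AGP21 with -6.56 ± 0.41. The carotenoid cleavage gene CCD8 was at least 111-fold and PELPK1 at least 66.9-fold higher at DAE28, and GER3 at least 232-fold and PRP2 at least 68.6-fold lower.

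Of 19 senescence-associated genes 17 rose and 1 fell in gvs1-1, with SAG29 at 8.10 ± 0.67, and of 31 senescence transcription factors 23 rose, with WRKY57 at 2.104 ± 0.13. Their medians were 1.68 and 1.71 (adjusted p = 0.243 with an estimated correlation for both). Of 23 autophagy genes 18 rose (median 0.51) and of 24 nutrient remobilisation genes 14 rose and 1 fell (median 0.58), both with an adjusted p = 0.295 with an estimated correlation. Of 27 abscisic acid genes 19 rose, 20 adjusted over the list alone, and 2 fell (median 1.04; adjusted p = 0.243 with an estimated correlation). Salicylic acid genes rose in 12 of 22 cases (median 1.72, and 0.990 without gvs1-1 DAE14 replicate 1; adjusted p = 0.551 with an estimated correlation), with GRX480 at 2.67 ± 0.42, and heat shock proteins in 5 of 12 (median 1.103; adjusted p = 0.460 with an estimated correlation), with HSP70 at 2.32 ± 0.27. Chlorophyll breakdown genes rose in 7 and fell in 4 of 14 cases (median 0.84), flavonoid genes rose in 5 and fell in 3 of 15 (3 and 3 adjusted over the list alone; median 0.76), and neither list passed.

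All 24 chlorophyll synthesis genes, 20 of 21 antenna genes, all 23 photosystem subunits, 19 of 20 carbon fixation genes and all 21 plastid ribosomal proteins fell in gvs1-1. Their medians were -1.81, -0.97, -0.999, -1.26 and -1.81, and the adjusted p with an estimated correlation was 0.243 to 0.255. The photosystem and antenna medians were -0.18 and -0.23 under quantile normalization. Cell division genes fell in 13 of 14 cases (median -2.17), vascular markers in 8 of 9 (median -4.04), epidermis markers in 5 of 6 (median -1.13) and guard cell markers in 4 of 8 (median -0.52), at an adjusted p of 0.243, 0.255, 0.255 and 0.441 with an estimated correlation. The guard cell and phloem markers in these counts included TGG1 with -5.88 ± 0.17 and SEOR1.

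With slide as a fixed block 8708 genes changed with age in gvs1-1, with scan day as a fixed block 9883, on scan day 1 alone 8929 and on slide 3 alone 6951. Scan day 1 and slide 3 held a single gvs1-1 DAE14 array, replicate 3, assumed to vary like the others. With slide as a block the age changes in gvs1-1 also rest on this array, so they are no separate check. With slide as a block the senescence-associated and photosystem medians were 1.78 and -1.08, and with scan day as a block 1.66 and -0.92. The salicylic acid call was lost with slide as a block (median 1.02), the guard cell call with scan day as a block (-0.23), and the epidermis call in the authors' table (-0.69) and without gvs1-1 DAE14 replicate 3 (-1.16). The heat shock call was lost with slide as a block and on slide 3 alone (0.85), with normexp (0.07), in the authors' table (0.44), and without gvs1-1 DAE14 replicate 1 (1.02) or gvs1-1 DAE28 replicate 2 (0.90).

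**Figure D2:**
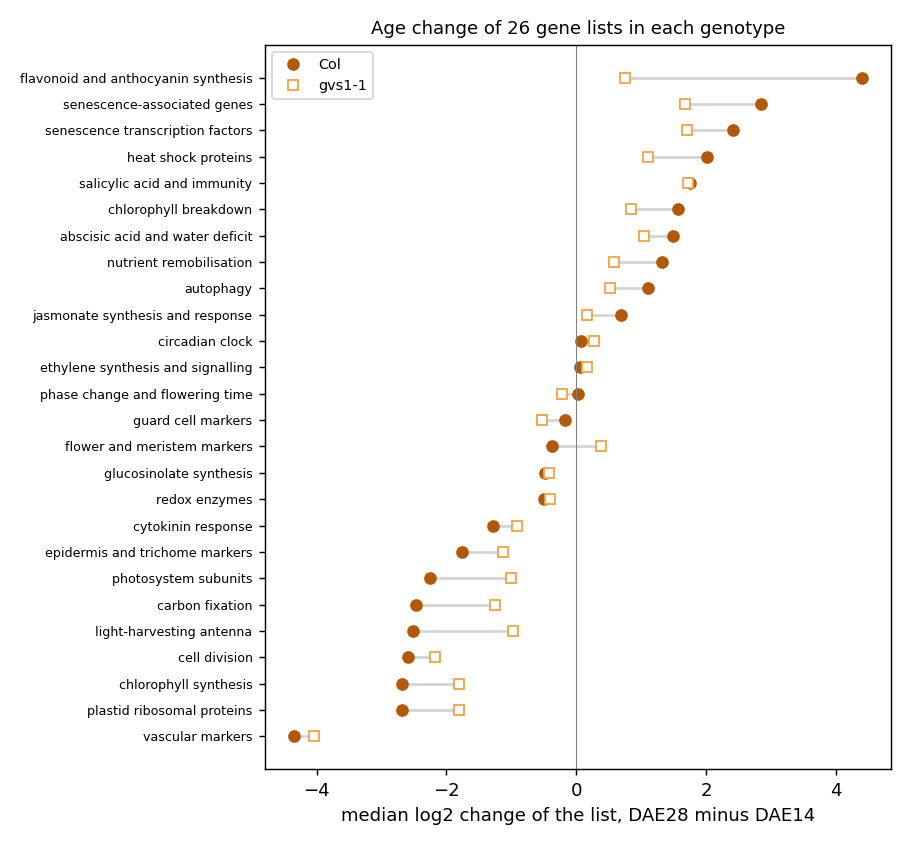
Median log2 change with age of 26 gene lists, in Col (filled circles) and gvs1-1 (open squares), joined by a grey line per list. The medians of the senescence-associated list were 2.84 and 1.68 and those of the photosystem list -2.25 and -0.999.

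At DAE14 few genes passed between the genotypes: 9 were higher and 51 lower in gvs1-1 at a limma adjusted p under 0.05. By limma 3194 genes had an unadjusted p under 0.05, more than a share of 0.05 of the 19152 tested. The small count therefore does not show that the genotypes were alike. Within the limit of a symbol, signal above background on every array compared and no overlap, the largest excess was that of MRD1, with a difference of 4.97 ± 0.64 (SE, n = 3 arrays per genotype; limma adjusted p = 0.020), followed by the brassinosteroid synthesis gene CYP90D1 with 1.54 ± 0.24 (adjusted p = 0.034). Lower in gvs1-1 within this limit were GTC2 with -1.97 ± 0.32, the photolyase PHR1 (AT1G12370) with -1.49 ± 0.25, the hexokinase-like gene HKL1 with -1.36 ± 0.16, the nitrile specifier NSP2 with -1.31 ± 0.18 and the plastid aldolase FBA2 with -1.21 ± 0.11. For FBA2 the mean difference over its 3 other kept probes was -0.43. TIM23-3 was at least 3.96-fold and ARI13 at least 3.34-fold lower. Of the 10 panel genes 0 passed by limma and 4 had an unadjusted p under 0.05: SAG12 was not well above background in either genotype, and among the others RBCS1A had the smallest adjusted p (-0.56 ± 0.11, 0.075).

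Photosynthesis genes lay somewhat lower in gvs1-1 at DAE14. Of 23 photosystem subunits 9 were lower, and 16 adjusted over the list alone, with PSAN at -1.04 ± 0.12 and PSAE-1 at -0.96 ± 0.11. Of 21 antenna genes 2 were lower (12 adjusted over the list alone), such as LHCB4.1 with -0.69 ± 0.11 (0.01 under quantile normalization), and of 20 carbon fixation genes 3 (10 adjusted over the list alone), such as RCA with -0.85 ± 0.12. Other kept probes of these named genes differed less. Their mean was -0.90 for PSAN (1 probe), -0.69 for PSAE-1 (3), -0.32 for LHCB4.1 (4) and -0.44 for RCA (8). For PSBW and PSBO1 the other probes differed more, at -1.26 and -0.96 against -0.73 and -0.74. For PSAD-1 and LHCA4 they were at -0.79 and -0.42 against -0.85 and -0.72. For PSBY, PSBQ-2, PSAO and the carbon fixation gene HCEF1 they were at -0.20, -0.18, -0.24 and -0.04 against -0.95, -0.90, -0.64 and -0.67. Several of these calls thus depend on the probe taken. The list medians were -0.64, -0.57 and -0.53, with adjusted p = 0.214, 0.405 and 0.265 with an estimated correlation. These 3 list calls depended on the scaling. They held with median centring (medians -0.58, -0.51 and -0.47) and with normexp (-0.58, -0.58 and -0.54), and were lost under quantile normalization (-0.02, 0.07 and 0.03) and in the authors' table (-0.08, -0.02 and -0.06). Jasmonate genes lay higher in gvs1-1, with a median of 0.61 (camera adjusted p = 1.1e-08; adjusted p = 0.214 with an estimated correlation). By limma 0 of their 26 members passed over all genes, 14 had an unadjusted p under 0.05, and 10 were higher adjusted over the list alone; TIFY7 (0.74 ± 0.16) and OPR3 (0.73 ± 0.18), a jasmonate synthesis enzyme, had the smallest adjusted p. The other 22 lists did not pass, with a camera adjusted p of 0.291 or more. Among them median and mean differed in sign for chlorophyll synthesis (0.05 and -0.07) and salicylic acid (-0.14 and 0.13), and the test's direction differed from the median for nutrient remobilisation (0.02, tested as lower) and abscisic acid (-0.02, tested as higher).

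The count at DAE14 moved with single arrays and with the batches. It was 9, 19 and 5 without Col DAE14 replicates 1, 2 and 3, 235, 18 and 50 without Col DAE28 replicates 1, 2 and 3, 25, 5 and 277 without gvs1-1 DAE14 replicates 1, 2 and 3, and 16, 16 and 39 without gvs1-1 DAE28 replicates 1, 2 and 3. It was 6 with slide and 2 with scan day as a fixed block, 4 on scan day 1 alone and 2079 with array weights. No slide held both Col DAE14 and gvs1-1 DAE14 arrays, so values with slide as a block are indirect here and rest on Col DAE28 replicate 1 as the link between slides. The share of higher calls was 15% here, 43.5% under quantile normalization and 38.9% in the authors' table. Of the calls, 3 of 6 with slide as a block, 2 of 2 with scan day as a block and 4 of 4 on scan day 1 alone were higher. The values on scan day 1 alone rest on 1 gvs1-1 array, replicate 3. With slide as a block the photosystem, antenna, carbon fixation and jasmonate medians were -0.90, -0.94, -0.91 and 0.89, with scan day as a block -0.69, -0.61, -0.58 and 0.72, and on scan day 1 alone -0.57, -0.42, -0.46 and 0.59.

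At DAE28 the lists of senescence genes lay lower and those of photosynthesis genes higher in gvs1-1 than in Col, at the preset correlation but not with an estimated one (adjusted p = 0.300 to 0.307). Not all members followed: 9 of 19 senescence-associated genes and 12 of 31 senescence transcription factors were lower, and 3 of the latter were higher. SAG12 differed by -9.15 ± 1.17, the senescence nuclease BFN1 by -4.91 ± 0.61, NAP by -1.61 ± 0.21 and NYE1 by -1.95 ± 0.18 (SE, n = 3 arrays per genotype; limma adjusted p = 0.00063, 0.00058, 0.00065 and 0.00022). RBCS1A was higher by 0.58 ± 0.11 and LHCB2.2 by 0.43 ± 0.14. In all, 3437 genes were higher and 2900 lower, 940 and 1048 of them by at least 2-fold. NAC6 (-1.24 ± 0.62, adjusted p = 0.15), WRKY53 (0.56 ± 0.53), PR1 (-0.13 ± 1.25), CCA1 (0.32 ± 0.20) and FT (-0.48 ± 0.37) did not pass.

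Within the limit of a symbol, signal above background on every array compared and no overlap, the largest excesses in gvs1-1 at DAE28 were MRD1 with 4.78 ± 0.64, XTH6 with 3.72 ± 0.45 and the defensins PDF1.2c, PDF1.2b and PDF1.3 with 3.72 ± 1.15, 3.70 ± 1.15 and 3.55 ± 1.14. The defensins depended on single arrays: without gvs1-1 DAE28 replicate 3 they differed by 2.41, 2.39 and 2.25 and their calls were lost. Within this limit the largest deficits besides SAG12 and BFN1 were the asparaginase ASPGB1 with -4.94 ± 1.02, the transporter OCT1 with -4.58 ± 0.80 and the terpene synthase TPS03 with -4.29 ± 0.57. The abscisic acid synthesis gene NCED2 was at least 54.1-fold and RGF3 at least 18.9-fold lower. With 1 array left out the log2 difference ranged from -8.85 to -5.72 for NCED2 and from -6.13 to -5.02 for RGF3. The size for NCED2 thus depends on single arrays. KNATM and HB53, not well above background in Col, were at least 3.36-fold and 1.89-fold higher, but with normexp their log2 differences were -0.21 and -0.37.

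Of 19 senescence-associated genes 9 were lower in gvs1-1 at DAE28 (median -0.82), and of 31 senescence transcription factors 12 were lower and 3 higher (median -0.46; 14 and 4 adjusted over the list alone), the latter including PIL6, also called PIF5, with 0.63 ± 0.08. Of 14 chlorophyll breakdown genes 8 were lower and 2 higher (median -0.69; 9 and 3 adjusted over the list alone), with NYC1 at -1.78 ± 0.17 and PPH at -0.88 ± 0.09. Autophagy genes were lower in 14 of 23 cases (median -0.53; 18 adjusted over the list alone), with APG7 at -2.32 ± 0.23. Nutrient remobilisation genes were lower in 14 and higher in 2 of 24 (median -0.65; 15 and 2 adjusted over the list alone), with the glutamate dehydrogenases GDH2 at -2.11 ± 0.20 and GDH1 at 1.19 ± 0.19. Abscisic acid genes were lower in 11 of 27 (median -0.33), with AAO3 at -1.37 ± 0.18, and heat shock proteins in 4 of 12 (median -0.98; 6 adjusted over the list alone), with MBF1C at -0.65 ± 0.14. With 1 array left out these medians ranged from -0.59 to -0.32 and from -1.21 to -0.64, and both lists still passed. These 7 lists passed at the preset correlation and had an adjusted p of 0.300 to 0.327 with an estimated correlation. Flavonoid genes were lower in 10 of 15 cases (median -3.56; 11 adjusted over the list alone; adjusted p = 0.393 with an estimated correlation), with MYB90 at -4.50 ± 0.96, but the result depends on the Col arrays. On scan day 1 alone the median was -0.88 and the call was lost, with 1 Col array left, replicate 1, whose mean of this list was the lowest (1.61, against 4.07 and 5.43).

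Chloroplast genes were higher in gvs1-1 at DAE28. Chlorophyll synthesis genes were higher in 17 of 24 cases, antenna genes in 16 of 21, photosystem subunits in 21 of 23, carbon fixation genes in 15 of 20 and plastid ribosomal proteins in all 21; adjusted over the list alone the counts were 19, 17, 21, 17 and 21. Their medians were 0.70, 0.90, 0.76, 0.68 and 0.81, with an adjusted p of 0.300 to 0.307 with an estimated correlation. CHLM differed by 1.38 ± 0.17, LHCB4.2 by 1.31 ± 0.18 and PSBQA by 1.36 ± 0.14. Jasmonate genes did not pass as a list (4 of 26 higher, 2 adjusted over the list alone; median 0.08). By limma 0 of 22 salicylic acid genes passed and 0 had an unadjusted p under 0.05, with a median of -0.12. Epidermis markers (1 of 6 higher, median 0.38) and guard cell markers (3 of 8 lower, median -0.18) did not pass as lists. Nor did cell division genes (1 of 14 lower, median 0.02) and vascular markers (1 higher and 1 lower of 9, median 0.21), both of which were tested as lower against the sign of their median.

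The count at DAE28 was 1763 with slide as a fixed block, 5281 with scan day as a fixed block and 4071 on scan day 1 alone; at this stage all gvs1-1 arrays were on slide 3 and all Col arrays on slides 1 and 2. Scan day 1 held 1 Col array of this stage, replicate 1, so its values rest on that sample. No slide held both genotypes at this stage, so values with slide as a block are indirect. They rest on gvs1-1 DAE14 replicate 3 as the link to slide 3, and slide and genotype cannot be told apart here. The photosystem and senescence-associated medians were 0.47 and -1.15 with slide as a block, 0.88 and -1.11 with scan day as a block, and 0.94 and -0.92 on scan day 1 alone. The share of higher calls was 54.2% here, 43.5% with median centring and 43.4% with normexp, which moved the median difference of all genes from 0.04 to -0.12.

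A set of 19 genes differed in the same direction between the genotypes at both stages, and 20 of the 51 genes lower in gvs1-1 at DAE14 were higher at DAE28. The set is part of the 60 calls at DAE14, so it depends on single arrays. Only 5 genes were called at DAE14 without Col DAE14 replicate 3, and likewise without gvs1-1 DAE14 replicate 2. The locus AT3G55920 was not well above background in Col at either stage and was at least 53.6-fold higher in gvs1-1 at DAE14 and 82.1-fold higher at DAE28. AT3G05170, also below background in Col, was at least 20.4-fold and 68.9-fold higher. AT5G03090, below background in Col at DAE14, was at least 3.999-fold higher there and differed by 3.97 ± 0.42 on the log2 scale at DAE28, and AT4G34540 differed by 2.17 ± 0.37 and 3.20 ± 0.37; MRD1 was also higher at both stages. Lower at both stages were AT3G28899 with -6.96 ± 0.60 and -5.54 ± 0.60, AT3G07820 with -2.82 ± 0.48 and -1.41 ± 0.48, AT3G55890 with -1.88 ± 0.22 and -1.04 ± 0.22, and GTC2 with -1.97 ± 0.32 and -1.04 ± 0.32. Without Col DAE28 replicate 1 the DAE28 differences of AT3G07820 and GTC2 were -0.83 and -0.65, and no longer passed. AT3G06830, below background in both genotypes at DAE14 and in gvs1-1 at DAE28, was at least 1.27-fold lower at DAE28. Independent lists would share 1.62 higher and 7.72 lower genes, against 8 and 11 here. They would hold 9.15 genes lower at DAE14 and higher at DAE28, against 20, so at this scaling more of the lower genes reversed than stayed lower. The lower genes included photosystem genes, whose list median at DAE14 was -0.02 under quantile normalization. With that scaling 32 of the 60 calls at DAE14 were kept and 26 genes were lower. The overlap was not counted there, so the reversal is given for the main scaling only. Across all genes the differences at the 2 stages, which share no arrays, correlated at 0.05.

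The age change itself differed between the genotypes for 3574 genes, tested as the interaction: the value was positive in gvs1-1 relative to Col for 1898 and negative for 1676. Among genes with a symbol that were well above background on every array, BFN1 had the lowest interaction (-5.39 ± 0.87, limma adjusted p = 0.0048). It was followed by ASPGB1 with -4.83 ± 1.44, SRG1 with -4.14 ± 0.89, TPS03 with -4.04 ± 0.80 and ZF14 with -4.03 ± 0.79. The highest among these were OFP15 with 3.36 ± 0.85, ELP with 3.30 ± 0.46, XTH6 with 3.29 ± 0.63, the carbonic anhydrase CA1 with 2.54 ± 0.73 and the auxin-response gene IAA29 with 2.50 ± 0.66. NAP (-1.62 ± 0.29) and NYE1 (-1.75 ± 0.25) rose less with age in gvs1-1 than in Col, and RBCS1A (1.15 ± 0.15) and LHCB2.2 (1.05 ± 0.20) fell less. SAG12 had an interaction of -8.09 ± 1.65, which rests on DAE14 levels below background. NAC6 (-1.49 ± 0.87), WRKY53 (-0.68 ± 0.76), PR1 (0.25 ± 1.77), CCA1 (0.86 ± 0.28) and FT (-0.83 ± 0.52) did not pass.

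All 23 photosystem subunits had a positive interaction (median 1.32), with PSAN at 1.80 ± 0.17 and PSAE-1 at 1.57 ± 0.15. So did 16 of 21 antenna genes (median 1.39), 15 of 20 carbon fixation genes (1.15), 13 of 21 plastid ribosomal proteins (0.90) and 9 of 24 chlorophyll synthesis genes (0.77), or 17, 18, 19 and 11 adjusted over the list alone. Under quantile normalization the photosystem, antenna and carbon fixation medians were 0.76, 0.53 and 0.68. The interaction was negative for 14 of 23 autophagy genes (median -0.66), with APG7 at -2.59 ± 0.33, 10 of 24 nutrient remobilisation genes (-0.56), 7 of 19 senescence-associated genes (-1.08), 6 of 14 chlorophyll breakdown genes (-0.65), with NYC1 at -1.91 ± 0.24, and 7 of 27 abscisic acid genes (-0.26). Adjusted over the list alone these counts were 16, 10, 10, 6 and 8. Senescence transcription factors had 11 negative and 3 positive interactions among 31 (median -0.67, and -0.44 without gvs1-1 DAE14 replicate 2; 12 and 3 adjusted over the list alone), with WRKY45 at -1.83 ± 0.21, and heat shock proteins 3 negative among 12 (-0.80). These lists passed at the preset correlation, and their adjusted p with an estimated correlation was 0.236 to 0.325. Jasmonate genes (2 of 26 negative, JAZ1 with -1.39 ± 0.40 and LOX3 with -1.32 ± 0.39; 0 adjusted over the list alone, median -0.42, and -0.25 without Col DAE14 replicate 1) and flavonoid genes (2 of 15 negative, PAP1 with -3.24 ± 0.63 and GSTF12 with -4.62 ± 1.44; 1 adjusted over the list alone, median -3.27) passed too, with an adjusted p of 0.389 and 0.419 with an estimated correlation. Interactions of cell division genes (median 0.12), vascular markers (median -0.02, mean 0.02) and epidermis markers (0.78, camera adjusted p = 0.054) did not pass as lists.

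The interaction count was 1044 with slide as a fixed block, 897 with scan day as a fixed block, 1489 on scan day 1 alone and 7624 with array weights. In the first 3 of these settings the interaction rests on 1 Col DAE28 array, replicate 1, and 1 gvs1-1 DAE14 array, replicate 3, since slide 2 holds the others. It was 1925 without Col DAE14 replicate 1, 2018 without Col DAE14 replicate 3, 2058 without gvs1-1 DAE14 replicate 2 and 2364 without Col DAE28 replicate 2. With slide as a block the photosystem and senescence-associated medians were 1.44 and -1.14, and the flavonoid median was -0.63 and no longer passed. The share of positive interactions was 53.1% here, 72.9% with slide as a block, 75.4% with scan day as a block, 75.1% on scan day 1 alone, 31.9% with median centring and 36.9% with normexp, which moved the median interaction of all genes from 0.07 to -0.11.

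Summed over 6526 genes that changed at least 2-fold with stage, the age response of gvs1-1 was 73.4% of that of Col. The age score of an array, the mean sign-aligned log2 value of these genes relative to Col DAE14, was 2.63 ± 0.13 in Col and 1.95 ± 0.10 in gvs1-1 at DAE28, and 0.00 ± 0.09 and 0.02 ± 0.21 at DAE14 (SD, n = 3). The exact permutation of genotype labels within stage, two-sided, gave p = 0.04, with 0.005 as the smallest its 400 assignments allow. On simulated data the same permutation test gave p = 0.1 for a true size of 70% and 0.055 for one of 100%. These were single simulated data sets, too few to show how well the test separates the sizes. The size was 65.1% with slide as a block (permutation p = 0.04) and 66.2% with scan day as a block (permutation p = 0.01). In both, labels were still permuted across the blocks, so these p-values are not exact for a blocked design. On scan day 1 alone, where Col DAE28 and gvs1-1 DAE14 are 1 array each, the size was 68.2%. Single arrays moved p across 0.05: it was 0.055 without Col DAE14 replicates 1 (74.98%) or 3 (74.4%), Col DAE28 replicates 1 (75.1%) or 2 (75.1%) and gvs1-1 DAE14 replicates 2 (75.2%) or 3 (76.0%), and 0.05 without Col DAE28 replicate 3 (72.6%).

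**Figure D3:**
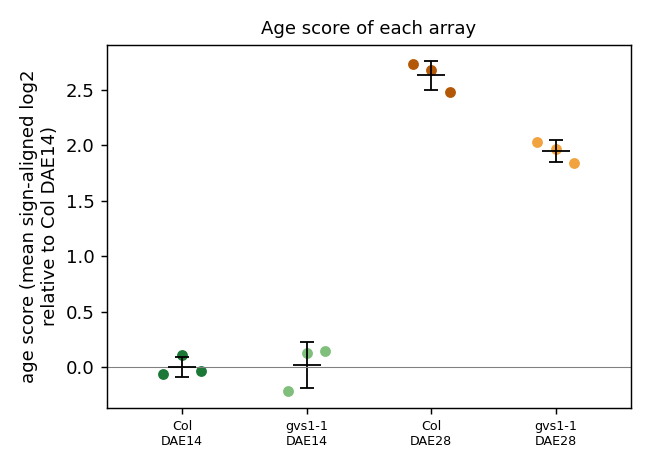
Age score of each array, the mean sign-aligned log2 value of 6526 stage-dependent genes relative to the mean of Col DAE14. Points are the 3 arrays of a group, the bar is the mean and the whiskers are the SD; at DAE28 the Col arrays lie between 2.48 and 2.73 and the gvs1-1 arrays between 1.84 and 2.03.

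Most genes that changed with age did so alike in both genotypes: 10011 genes changed in the same direction and 89 in opposite directions. Independent lists would share 2146 rises and 2082 falls, against 4905 and 5106 observed, and the changes, from comparisons that share no arrays, correlated at 0.90 across genes. Of the 2900 genes lower in gvs1-1 at DAE28, 2471 rose with age in Col (1036 for independent lists), and of the 3437 higher genes 2883 fell (1246 for independent lists). Both of these comparisons use the Col DAE28 arrays; their covariance was -1.02 against a simulated -0.04 for unchanged groups, and their correlation -0.71 against a simulated -0.50. The age change in gvs1-1 and the genotype difference at DAE28 share the gvs1-1 DAE28 arrays, with a covariance of -0.44 against a simulated 0.04 and a correlation of -0.41 against 0.50. With 3 arrays the shared group could not be split into parts of 2 arrays each, so part of each overlap may come from the shared arrays.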

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

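The comparison of gene sets and the shares per list that end this part, and the sorting of splits by their DAE28 arrays, were chosen after the result was seen; the other tests here were fixed before.

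These results stood out because the age change differed between Col and gvs1-1 in a test of the difference itself. The interaction passed for 3574 genes, and the age response of gvs1-1 was 73.4% of that of Col. The list medians of the interaction were -1.08 for senescence-associated genes, -0.67 for senescence transcription factors, -0.65 for chlorophyll breakdown, -0.66 for autophagy, -0.56 for nutrient remobilisation, -0.42 for jasmonate, -0.26 for abscisic acid, -0.80 for heat shock proteins and -3.27 for flavonoids. They were 0.77 for chlorophyll synthesis, 1.39 for antenna, 1.32 for photosystem, 1.15 for carbon fixation and 0.90 for plastid ribosomal genes. These lists passed at the preset correlation; with an estimated correlation 0 of them passed (adjusted p = 0.236 to 0.419), and by fry 12 of the 14 did, jasmonate (0.078) and flavonoids (0.111) being the others.

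Among 100 drawn splits of the genotype labels within each stage, the real split was the 1 with the most interaction calls, 3574 against 2942 for the highest other. It argues against a chance parting of the arrays at both stages at once, but not at a single stage. This rests on the DAE28 arrays: the 8 splits that kept them parted by genotype, the real one included, called 1737 to 3574 genes, and the other 92 called 0 to 2. Those 8 are too few to show whether the parting at DAE14 adds to the count, so much of it may reflect the genotype difference at DAE28. The splits take no account of slide or scan day, and the count was 1044 and 897 with these as fixed blocks. For the remaining comparisons the 10 splits of 6 arrays are too few for a share under 0.05; the real split was the 1 with the most calls in each. The real and highest other counts were 13786 and 0 for age in Col, 11750 and 0 for age in gvs1-1, 60 and 27 for genotype at DAE14, and 6337 and 1 for genotype at DAE28.

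The smaller age response of gvs1-1, at 73.4% of that of Col, was set against batch and scaling. With slide as a fixed block it was 65.1% and with scan day as a fixed block 66.2%, where a batch origin would have needed 95% or more. With either block the genotype difference in age change rests on 1 Col DAE28 array and 1 gvs1-1 DAE14 array, which limits what these values exclude. It was 72.2% under quantile normalization and 73.6% with median centring. Median centring shifts whole arrays, which nearly cancels over the 2813 rising and 3713 falling genes of the main setting. That value could hardly have moved and decides nothing. The value under quantile normalization argues against scaling between arrays as the whole origin. The exact permutation of genotype labels gave p = 0.04. With the replicate number as a block the permutation p was 0.09, but labels were still exchanged across replicate numbers, so it is not exact for a blocked design. Without single arrays such as Col DAE14 replicate 1 the exact permutation p was 0.055, so the p of 0.04 carries little weight. A slower or later course of senescence in gvs1-1 may underlie the pattern, but with 2 stages a delay and a lower final level cannot be separated, and each remains an untested hypothesis.

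The 64 antenna, photosystem and carbon fixation genes kept 51.1% of the Col age change in gvs1-1, and 23 cell division and vascular genes kept 97.5%, at an exact permutation p = 0.005 for the difference, the smallest that 400 assignments can give. The sets were chosen after their interaction medians were seen, so this p restates the choice and shows no difference between kinds of genes. Over the 17 cell division and vascular genes well above background on all arrays the share was 97.5% and the exact permutation p = 0.005. The shares were 53.6% and 101.7% with median centring (p = 0.005), 49.6% and 125.8% with normexp (0.005), 53.5% and 99.5% in the authors' table (0.02) and 51.8% and 101.9% under quantile normalization (0.08). Over the 8 lists that passed as falling in Col, the share of the mean change was 46.5% for photosystem, 51.2% for antenna, 56.1% for carbon fixation, 59.4% for epidermis and trichome, 65.4% for plastid ribosomal, 66.6% for chlorophyll synthesis, 95.3% for cell division and 99.4% for vascular genes. These shares start from each genotype's own DAE14 level. Relative to Col DAE14, the list means in gvs1-1 at DAE14 were -0.59 for photosystem, -0.43 for antenna, -0.42 for carbon fixation and -0.29 for epidermis genes. Those of the remaining lists lay between -0.07 and 0.10. At the main scaling part of the smaller shares thus reflects a lower start. Under quantile normalization the photosystem median at DAE14 was -0.02, yet the 64 genes kept 51.8%. The epidermis list, which is not photosynthetic, lies with the plastid lists, so whether gene sets lose different shares stays open.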

How the results depend on the processing

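Slide as a random block, scan day 1 alone and slides 1 and 3 alone were chosen after seeing the data. Scan day 1 held 1 Col DAE28 array and 1 gvs1-1 DAE14 array, so values on it rest on these. The cause of the changes below was not tested unless stated. Asking also for a 2-fold change left 7723 genes for age in Col, 5458 for age in gvs1-1, 29 for genotype at DAE14, 1988 for genotype at DAE28 and 1753 for the interaction. Testing each probe, which raises the number of tests, gave 21564, 18071, 213, 9582 and 5674. The count at DAE14, 60 here, was 19 with median centring, 5 with normexp, 20 without the filter on dim probes, 32 with the mean of a gene's probes, 2079 with array weights, 36 in the authors' table, 2 with only the 2 groups compared, 6 with slide as a fixed or a random block, 2 with scan day as a fixed block and 4 on scan day 1 alone. The count at DAE28 was 3794 with normexp, 1763 with slide as a fixed block and 4071 on scan day 1 alone. The interaction count was 1513 with normexp, 7624 with array weights, 1044 with slide as a fixed block, 2204 with slide as a random block, 897 with scan day as a fixed block and 1489 on scan day 1 alone. Age in gvs1-1 gave 6951 genes on slide 3 only, where 4 arrays were used. Counts in the other settings stayed within 1.5 times, apart from the replicate block at DAE14 and single arrays left out, both given below.

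The deviations of each array from its group mean were correlated across genes between groups. Of 18 pairs of same-numbered samples 4 had deviations that correlated above 0.1, with a range of -0.27 to 0.51. For 4 arrays the deviations correlated best with those of an array of their own number. Between Col and gvs1-1 at DAE14 the deviations of the pairs correlated at 0.51, 0.38 and -0.10, so replicates 1 and 2 moved together there. With the replicate number as a block, genotype at DAE14 gave 14 genes and the relative size of the age response was 73.5% (permutation p = 0.09, with labels exchanged across replicate numbers). It was 75.5% (0.06) with normexp and 68.2% (0.0625) on scan day 1 only; in the other settings but single arrays left out p stayed at 0.04 or less.

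Leaving out 1 array at a time gave 12712 to 13828 genes for age in Col, 10398 to 12263 for age in gvs1-1, 5 to 277 for genotype at DAE14, 4811 to 6479 for genotype at DAE28, 1925 to 4919 for the interaction and a relative size of 69.0% to 76.0%. The lowest count at DAE14 was that without Col DAE14 replicate 3 or gvs1-1 DAE14 replicate 2 and the highest that without gvs1-1 DAE14 replicate 3. The lowest count for age in Col and for the interaction was that without Col DAE14 replicate 1, for age in gvs1-1 that without gvs1-1 DAE28 replicate 1 and for genotype at DAE28 that without gvs1-1 DAE28 replicate 3. The highest for age in gvs1-1 and for the interaction was that without Col DAE28 replicate 1, and for age in Col and genotype at DAE28 that without gvs1-1 DAE14 replicate 1.

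Of the 63 list calls, 1619 of 1656 values across settings kept their direction and side of the threshold, 35 lost the call and 2 reversed. The reversed ones were the antenna (0.0744) and carbon fixation (0.0274) lists at DAE14 under quantile normalization. Some lists not called at DAE14 passed in other settings with a median opposite in sign to that of the main setting. This held for chlorophyll synthesis with slide (-0.41) or scan day (-0.21) as a block, on scan day 1 alone (-0.15) and without gvs1-1 DAE14 replicate 1 (-0.16, against 0.14 as the highest with 1 array left out). The same held for autophagy (-0.23) and flavonoids (-3.11) with slide as a block, and for salicylic acid with scan day as a block (0.33), on scan day 1 alone (0.47) and without gvs1-1 DAE14 replicate 1 (0.58, against -0.40 as the lowest with 1 array left out). Interaction calls were lost for chlorophyll breakdown with normexp (-0.58), jasmonate with normexp (-0.52), in the authors' table (-0.30) and with array weights (-0.37), abscisic acid with array weights (-0.05), and flavonoids with either block or on scan day 1 alone (-0.63). Salicylic acid for age in gvs1-1 was lost with array weights (1.13). LHCB2.2 reversed for age in gvs1-1 under quantile normalization (0.21), and KNATM (-0.21) and HB53 (-0.37) reversed at DAE28 with normexp.
LOX2 reversed for age in Col (0.65) and LHCB4.1 at DAE14 (0.0130) under quantile normalization. Of 4636 values for 171 called results of named genes, 4097 kept direction and call, 534 lost the call and 5 reversed. Losses with 1 array left out concerned WRKY53 for age in Col, PDF1.2c, PDF1.2b, PDF1.3, LHCB2.2, AT3G07820, GTC2 and HB53 at DAE28, OFP15, CA1, IAA29, ASPGB1, JAZ1, LOX3 and GSTF12 for the interaction, and 114 values at DAE14.

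Signal over background limits these results. Without the filter on dim probes 25346 genes were tested and the median of all genes moved to -0.33 for age in Col, -0.13 for age in gvs1-1, 0.12 for genotype at DAE28 and 0.20 for the interaction.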

Other observations

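The bootstrap interval for the photosystem list at DAE14 and every test of chromosomes were chosen after the result was seen; the other tests of this part were fixed before.

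The cytokinin, jasmonate and ethylene lists did not pass for age in either genotype. Of 17 cytokinin genes 4 rose and 11 fell in Col (median -1.29, camera adjusted p = 0.098), with the response regulator ARR4 at -1.90 ± 0.10 and the synthesis gene IPT3 at -2.80 ± 0.23 (SE, n = 3 arrays per group). In gvs1-1 5 rose and 11 fell (12 adjusted over the list alone; median -0.91). At DAE28, 8 were higher and 2 lower in gvs1-1 (median 0.58, camera adjusted p = 0.075), with IPT3 at 1.44 ± 0.23 and the cytokinin oxidase CKX5 at -2.40 ± 0.37; the interaction was positive for 3 and negative for 1 (4 and 2 adjusted over the list alone; median 0.53). Of 26 jasmonate genes 13 rose and 5 fell in Col (median 0.69, camera adjusted p = 0.147), with the repressor JAZ5 at 3.23 ± 0.41 and the lipoxygenase LOX2 at -0.71 ± 0.11, which was 0.65 under quantile normalization. In gvs1-1 4 rose and 6 fell (4 and 4 adjusted over the list alone), with a median of 0.16 and a mean of -0.17. Of 18 ethylene genes 4 rose and 2 fell in Col (median 0.06), with the synthesis gene ACS2 at 5.63 ± 0.43, and 6 rose and 4 fell in gvs1-1 (median 0.16), with ACS2 at 3.01 ± 0.43; 1 was higher and 3 lower in gvs1-1 at DAE28 (median -0.10).

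Other lists were mixed and did not pass in Col, gvs1-1 or between them, except that guard cell markers passed for age in gvs1-1 at the preset correlation but not with an estimated one (adjusted p = 0.441). Of 15 glucosinolate genes 2 rose and 9 fell in Col (median -0.49), with the regulator MYB29 at -2.05 ± 0.17, and 1 rose and 7 fell in gvs1-1 (1 and 5 adjusted over the list alone; median -0.41). At DAE28 3 of them were higher (1 adjusted over the list alone), with a median of -0.01 and a mean of 0.06. Of 16 clock genes 4 rose and 5 fell in Col (median 0.07), with FKF1 at 1.21 ± 0.14 and TOC1 at 1.08 ± 0.16; 5 rose and 1 fell in gvs1-1 (median 0.27). Of 13 redox enzymes 4 rose and 5 fell in Col (median -0.50), with the superoxide dismutase FSD1 at -1.81 ± 0.14 and the oxidase RBOHD at 1.03 ± 0.12, and 2 rose and 6 fell in gvs1-1 (median -0.41). Of 7 phase change genes 2 rose and 2 fell in Col (median 0.02, mean -0.12), with the flowering gene AGL8 at 1.54 ± 0.14 and SPL3 at -1.58 ± 0.22. In gvs1-1 2 of them rose and 1 fell (2 and 0 adjusted over the list alone; median -0.22, mean 0.07). Of 8 guard cell markers 1 rose and 3 fell in Col (median -0.17), with TGG1 at -6.01 ± 0.17. Of 3 flower markers 1 rose in Col, PI with 2.43 ± 0.50 (median -0.38, mean 0.46), and 1 fell in gvs1-1 (0 adjusted over the list alone; median 0.38).

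Photosystem genes lay lower in gvs1-1 at DAE14, with a median of -0.64 over 23 genes, and batch and bright-probe effects were weighed against a genotype difference. The median was -0.69 with scan day as a fixed block, and the list mean relative to Col DAE14 was -0.54 on the gvs1-1 array scanned on day 1, as all Col arrays of this stage were, and -0.60 and -0.61 on those of day 2. This argues against scan day as the whole origin. The median was -0.90 with slide as a fixed block, but no slide held both Col DAE14 and gvs1-1 DAE14 arrays and that value is linked through 1 array, Col DAE28 replicate 1, so slide and genotype cannot be told apart here. If bright probes read low on the gvs1-1 arrays, genes of the same brightness outside the plastid lists should lie low too; the median of 136 such genes was -0.11. That met the bound of -0.16 set beforehand for excluding this, but its bootstrap interval, -0.21 to -0.05 over 10000 draws, spans the bound; under quantile normalization the list median was -0.02 and that of 140 matched genes 0.14. The list lay below the matched genes in both scalings, but with that interval compression of bright probes and a genotype difference cannot be told apart, and how far photosystem genes may lie lower in gvs1-1 depends on the scaling.

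Of the 19 genes that differed the same way between the genotypes at both stages, 9 lie on chromosome 3, or 47.4% against 20% of tested genes. This was looked for first among the 60 genes called at DAE14, 19 of them on chromosome 3 (two-sided Fisher's exact p = 0.0337, 0.168 adjusted over 5 chromosomes), and then among the 19 (0.00652, and 0.0652 adjusted over the 10 tests of both sets), so chance is not excluded. A segment linked to the mutation could gather such genes, but 0.151 of 10000 random draws had as small a median distance in gene order (a median of 89 positions to the nearest other, against 166 in draws; 0.181 for the 60 genes), which leaves it open. A variant under a single probe might mimic a difference, but only 1 of the 9 genes, AT3G11930, named after its values were seen, has another kept probe, so variants under single probes stay open. Both sets rest on the calls at DAE14, which numbered 5 to 277 with 1 array left out, so they depend on single arrays. The locus of gvs1 is not given in the sources used here, and no other explanation was tested.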
